A study of Oncorhynchus mykiss with 8 samples.

How the data were processed

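RNA from liver and muscle of rainbow trout of the Lyndon strain, all offspring of neomales, was compared between small and large fish on 8 arrays with 2 colours. Per the labels' protocols, total RNA was extracted with Trizol, mRNA was isolated with magnetic columns, and cDNA was labelled directly with Alexa Fluor 555 or Alexa Fluor 647. Each array held a pool of small fish and a pool of large fish of one tissue, and each pool held mRNA of 5 fish. From the titles and labels, every pair of pools was read as hybridised on 2 arrays with the dyes exchanged, which gives 2 pool pairs per tissue and 4 pool pairs in all. The series' own summary of its design counts 4 replicates of each size without dividing them by tissue. It was read as 2 pools per size and tissue, which the labels do not state, so the number of independent pools is an assumption.

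The deposited table gives 1 value per array and row, which was read as a log2 ratio of both channels. The unit was found from the values: with a tolerance of 0.05 thousandths, which was widened after a narrower one had been tried, 2 to the power of the value fell on a ratio rounded to 3 decimals for 98.1 to 99.2% of the values of moderate size on each array. The same power of the value with its sign turned fell there for 10.0 to 11.2% of them. No header or label states the scanner software, the background correction, the normalization or why cells are empty. Nor do they state which channel is the numerator, or whether the authors had turned the arrays with exchanged dyes. No intensity or background signal was used here, so no filter on dim spots could be applied, and the precision is limited by the number of pool pairs and by their spread.

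The table had 43,663 rows, of which 60 control spots were left out, so that 43,603 probes remained. Gene symbols came from an old platform annotation, which named 221 probes with 1 symbol and left 43,382 without one. No probe had several symbols. The named probes carried 174 distinct symbols, and 104 of these probes had only a locus placeholder. None of their accessions, 0 in all, matched the reference annotation (assembly USDA_OmykA_1.1), so the symbols of the platform were kept and no position is given.

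Each pool pair was reduced to 1 value per probe, because its 2 arrays hold the same RNA. In the design fixed beforehand the deposited values were taken as ratios in a fixed dye direction, so the sign of the array with large fish in the 647 dye was turned and the 2 arrays were averaged. These are called turned values. The mean of the 2 arrays with no sign changed is the dye effect under that design. A check fixed with the design said that this dye part should correlate more between liver and muscle than the turned part. It did not, so the counts, the named genes, the camera test and the agreement are also given with the deposited values taken as already turned, that is, with no sign changed. Other values are turned unless stated otherwise. Because the direction of the ratio is unknown, positive means positive as deposited on the arrays titled large versus small, and no value is called higher in large or in small fish.

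The 4 pair values of a probe were fitted with limma 3.58.1 in R 4.3.3, with tissue as the group, no intercept and default empirical Bayes moderation. Each tissue's mean was tested against 0 and the liver mean was tested against the muscle mean, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A probe was tested in a tissue if it had a value on all 4 arrays there. The fit had 2 residual and 2.21 prior degrees of freedom. Members of 17 gene lists were matched by symbol, averaged over their probes, and tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, where at least 5 genes were measured. The lists were the growth hormone and IGF axis, myofibril and contraction, cytosolic ribosomal proteins, oxidative phosphorylation, glycolysis and gluconeogenesis, lipid synthesis and transport, protein breakdown, liver-secreted plasma and acute-phase proteins, interferon response and antigen presentation, cell cycle, chaperones, collagens and extracellular matrix, oestrogen-induced egg proteins, and markers of red blood cells, exocrine pancreas, leukocytes and adipocytes.

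Genes were named by a rule: among named probes past the threshold with 1 sign on all 4 arrays, the 12 with the largest mean on each side, and where fewer passed, the 5 per side with the lowest p and 1 sign on all 4 arrays. The rule added the 2 genes of each list with the lowest p, igf1, igfbp1, ghr, mstn and vtg where measured, and up to 2 unnamed probes per side. Locus placeholders were left out of the rule as unknown. Genes outside the rule are said to be chosen after their values were seen. For the values as deposited the same rule was applied a second time. The design, the lists, the naming rule and the alternatives to be tried, other than those said to be added, were fixed before the data were examined. While the values were being explored, the version with no sign changed was for a time treated as the leading one, and the fixed design was then restored.

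The fit was tested on simulated data, with 200 of 34,757 probes changed. Each probe's spread was drawn from limma's estimate over both tissues and was the same in liver and muscle. The real liver arrays varied more than the muscle arrays, so the shares do not describe the power in liver itself. In liver it recovered 1.5% of the probes changed by 1 on the log2 scale, 65.7% of those changed by 2 and 81.8% of those changed by 3. In muscle the shares were 1.5%, 73.1% and 93.9%. Alternatives covered centring, scaling, the filter on missing values, robust moderation, the sign, all 8 arrays with the pool pair as a random block or as independent arrays, the gene level, each tissue alone, the replicate number as a block, a threshold of 0.10, and leaving out each pool pair. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.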

Results

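Transcript ratios of small against large neomale offspring were measured in liver and muscle on 8 arrays, 4 per tissue, which make 2 pool pairs per tissue with the dyes exchanged within each pair. Every pool combined mRNA of 5 fish. Of 43,603 probes, the liver arrays lacked a value for 2296 to 3035 and the muscle arrays for 428 to 845. The standard deviation of the log2 ratios across probes was 0.63, 0.74, 0.55 and 0.92 on the liver arrays and 0.32 to 0.33 on the muscle arrays. Array medians were 0.11, -0.08, 0.08 and -0.05 in liver and between -0.01 and 0.01 in muscle, in the order replicate 1 with large fish in the 555 dye, replicate 1 with large fish in the 647 dye, and likewise for replicate 2. Scale and centring are thus those of the deposited values, and their direction is unknown.

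The first question was which liver transcripts differed between small and large fish. No probe passed an adjusted p of 0.05, so the genes below are given as values. Blank control spots also changed sign with the dyes in liver, so the turned liver values may hold a part other than size. Where both arrays of a pair had a value, these spots were positive once turned, like spp2, pax7, gnrh, tyrp-1b and gdh2 below. Whether these genes lay near the blank signal is unknown, since no intensities were used. With the sign of the arrays with large fish in the 647 dye turned, the largest deviations among the genes with the lowest p lay on the negative side. The mean of fkh was -1.03 ± 0.11 (SD, n = 2 pool pairs), a 2.04-fold ratio. One probe of hsp90b, a heat shock chaperone, had a mean of -0.99 ± 0.25, and cyp1a, an enzyme that oxidises foreign compounds, had -0.81 ± 0.45. The gluconeogenic enzyme pck2 had -0.67 ± 0.08 and mx2, an interferon-induced antiviral protein, -0.42 ± 0.03. On the positive side, spp2, a secreted phosphoprotein, had a mean of 0.64 ± 0.41 and pax7, a transcription factor of muscle stem cells, 0.58 ± 0.11. The gonadotropin-releasing hormone gene gnrh had 0.48 ± 0.08, tyrp-1b, of melanin synthesis, 0.37 ± 0.17, and a probe of gdh2, a glutamate dehydrogenase, 0.33 ± 0.05. Each of these 10 genes had, at the probe given, 1 sign on all 4 turned arrays, and their adjusted p in limma ranged from 0.160 for fkh to 0.207 for tyrp-1b. With no sign changed, the liver means of these probes were -0.04 for fkh, -0.16 for hsp90b, -0.67 for cyp1a, -0.11 for pck2, -0.07 for mx2, -0.09 for spp2, -0.17 for pax7, 0.14 for gnrh, -0.01 for tyrp-1b and 0.15 for gdh2. Apart from cyp1a, their size, and for spp2, pax7 and tyrp-1b their sign, thus rests on the turn, and fkh has a 1.03-fold ratio without it. The deposited values of cyp1a were -2.10 and -0.86 with large fish in the 555 dye, against 0.16 and 0.13 in the 647 dye. Its deviation thus came almost wholly from 1 dye orientation under either reading. Of the unnamed probes, A_05_P289762 had the mean -2.51 ± 0.19 and A_05_P258549 the mean 2.34 ± 0.22, both with an adjusted p of 0.160 in limma. With no sign changed they had 2.03 ± 0.04 and -0.68 ± 1.95, both of the other sign. The deposited values of A_05_P289762 were 4.44 and 4.64 with large fish in the 647 dye, against -0.31 and -0.64 in the 555 dye.

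Probes of one gene did not always give one value in liver. Besides the hsp90b probe above, the others, chosen after their values were seen, had means of -0.39 ± 1.11 and -0.42 ± 0.27. The second probe of cyp1a gave -0.86 ± 0.88, while the second of pck2 gave -0.64 in both pool pairs. The second probe of gdh2 had the other sign, -0.16 ± 0.81, and the gene-level mean of gdh2 was 0.09.

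**Figure D1:**
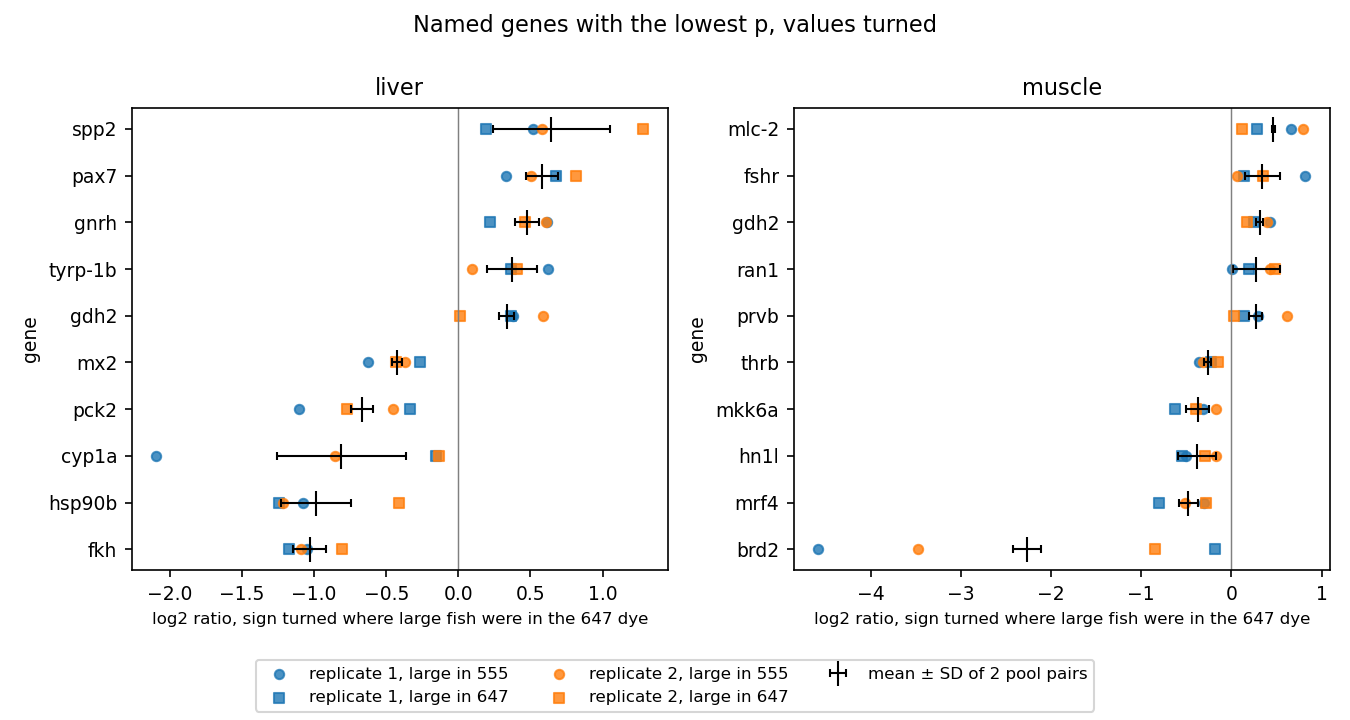
Log2 ratios (horizontal axis) of the 10 named genes per tissue with the lowest p and 1 sign on all 4 turned arrays; circles are arrays with large fish in the 555 dye, squares those with large fish in the 647 dye with the sign turned, colours are the replicates, and black marks are the mean ± SD of 2 pool pairs. In liver fkh has the lowest mean (-1.03), and in muscle the array values of brd2 lie apart by dye orientation (mean -2.27).

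In limma 0 of 36,053 liver probes passed the threshold, while 7346 had an unadjusted p under 0.05 against 1802.7 expected by chance, 3962 of them positive and 3384 negative. These counts rest on a spread shared with muscle: with liver fitted alone 2646 had such a p, 1072 positive and 1574 negative, and 0 passed. The balance of signs also rests on the centring, since with each array centred on its median 2252 were positive and 4735 negative. The lowest adjusted p was 0.160 in the shared fit and 0.600 alone. A fit of all 8 arrays with the pool pair as a random block passed 159 liver probes, and counting the arrays as independent passed 138. The correlation that limma estimated between the arrays of a pair was -0.026. Both fits thus count arrays that hold the same RNA almost as separate replicates. With replicate 2 taken from its array with large fish in the 555 dye alone, a choice made after seeing the data, 1539 passed, 1314 of them negative. A dye effect of replicate 2 is not averaged out in that fit, so this count is confounded with dye. With either liver pool pair left out, 7651 or 7964 passed.

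With the deposited values taken as already turned, limma also passed 0 liver probes, with 3596 at an unadjusted p under 0.05 and a lowest adjusted p of 0.245. Fitted alone, a choice made after seeing the data, liver had 1531 on this basis, fewer than chance gives, and a lowest adjusted p of 0.840. The genes with the lowest p on this basis were other ones. On the positive side a probe of mlc-2, a myosin light chain, had a mean of 1.13 ± 0.97, which rests on the value of 3.39 on the array of replicate 2 with large fish in the 647 dye, against 0.26 to 0.50 on the other 3. The myogenic factor myf5 had 0.36 ± 0.31. The interferon regulatory factor irf-2 had 0.21 ± 0.03, a transferrin (trf) probe 0.25 ± 0.13 and the follicle-stimulating hormone receptor fshr 0.10 ± 0.01. On the negative side were a probe of trp-i with -1.12 ± 1.37, an alpha globin (hba) probe with -0.54 ± 0.22 and fxyd9b with -0.24 ± 0.04. The second probe of trp-i, chosen after its values were seen, had 0.01 ± 0.96. Other probes chosen in this way had -0.20 ± 0.54 and -0.33 ± 0.65 for trf and 0.07, 0.07 and -0.05 for mlc-2. Those of hba had -0.67 ± 0.10 and 0.06 ± 0.04. Turned, the probes of mlc-2, irf-2, fshr and hba given first had means of the other sign (-0.81, -0.13, -0.08 and 0.07). No further named gene had negative values on all 4 liver arrays. The unnamed probes A_05_P457777 and A_05_P399667 had means of 1.93 ± 0.09 and -1.97 ± 0.06. Turned, these were -1.17 and -1.43.

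The second question was the same for muscle. The bromodomain gene brd2 had the largest turned deviation of a named gene there, with a mean of -2.27 ± 0.16 (SD, n = 2 pool pairs) and an adjusted p in limma of 0.709. Its deposited values were -4.58 and -3.47 on the arrays with large fish in the 555 dye but 0.18 and 0.85 on those with the dyes exchanged, so the deviation came almost wholly from one dye orientation. The myogenic factor mrf4 had a mean of -0.48 ± 0.11, a probe of hn1l -0.38 ± 0.21, the kinase gene mkk6a -0.37 ± 0.13 and the thyroid hormone receptor gene thrb -0.26 ± 0.04. Positive means belonged to a probe of mlc-2 (0.47 ± 0.01), to fshr (0.35 ± 0.19), a probe of gdh2 (0.31 ± 0.04), ran1 (0.28 ± 0.26) and the parvalbumin gene prvb (0.27 ± 0.07). The other mlc-2 probes, chosen after their values were seen, had means of 0.30, 0.06 and -0.12. Of the second probes, that of gdh2 had -0.47 ± 0.16, which makes its gene-level mean -0.08, and that of hn1l had -0.08 ± 0.07. Apart from brd2, all of these muscle genes had an adjusted p of 1. With no sign changed the muscle means of these probes lay between -0.07 (thrb) and 0.26 (mlc-2), apart from brd2 with -1.76, and those of mrf4, hn1l, mkk6a and ran1 had the other sign (0.07, 0.04, 0.13 and -0.06). The unnamed probes A_05_P483962 and A_05_P309967 had means of 1.26 ± 0.06 and -1.15 ± 0.14. With no sign changed these were -0.08 and -0.10.

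In limma 0 of 41,652 muscle probes passed, and 1885 had an unadjusted p under 0.05 against 2082.6 expected by chance. When muscle was fitted alone, without the wider spread of liver, 5046 had such a p and 3 probes passed, all negative. These were brd2 with an adjusted p of 0.0436, and the unnamed A_05_P335732 (mean -1.71) and A_05_P466372 (mean -1.59) with 0.0463 and 0.0492. The deposited values of A_05_P335732 were -3.59 and -3.28 on the muscle arrays with large fish in the 555 dye. With the dyes exchanged they were -0.15 and 0.14. Those of A_05_P466372 were -2.07 and -3.28, against 1.05 and -0.04 with the dyes exchanged. As for brd2, these deviations thus came mostly from one dye orientation. After scaling the arrays to one spread brd2 alone passed (mean -3.13, adjusted p 0.0201).

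With the values taken as already turned, limma passed 0 muscle probes, with 680 at an unadjusted p under 0.05 and a lowest adjusted p of 1, or 1239 with muscle fitted alone. The glycolytic enzyme gapdh had the lowest p of the named genes, with a mean of -0.86 ± 0.03 (1.82-fold, n = 2 pool pairs). The desaturase fadsd6 had -0.59 ± 0.09, the immunoproteasome gene psmb8b -0.28 ± 0.18, a probe of fxyd12a -0.13 ± 0.01 and a probe of the oestrogen receptor gene esr1 -0.11 ± 0.02. On the positive side were ahr2d (0.34 ± 0.31), a receptor for aryl hydrocarbons, the lipid sensor pparb2a (0.26 ± 0.04), a probe of mx1 (0.25 ± 0.11), a probe of mlc-2 (0.21 ± 0.27) and alp (0.19 ± 0.08). The second probes of fxyd12a, esr1 and mx1, chosen after their values were seen, had the other sign, with means of 0.13, 0.15 and -0.04. The sign of gapdh thus rested on the reading, since its turned mean was 0.64 ± 0.11, and so did those of the probes of mx1 and fxyd12a, with turned means of -0.09 and 0.04. Among the unnamed probes A_05_P429727 had 1.22 ± 0.15 and A_05_P253514 had -1.11 ± 0.17. Turned, these were 0.36 and 0.02. The locus LOC100136569, chosen after its values were seen, had values from -3.25 to -1.79 on all 4 muscle arrays at 2 of its 3 probes, with means of -2.37 ± 0.38 and -2.35 ± 0.51, about 5.18-fold and 5.12-fold. Their turned means under the fixed design were -0.20 ± 0.24 and -0.37 ± 0.23, or 1.15-fold and 1.30-fold. Both had an adjusted p of 1. Its remaining probe had -0.39 ± 0.04 in muscle, and the first probe had 0.01 ± 0.03 in liver.

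**Figure D2:**
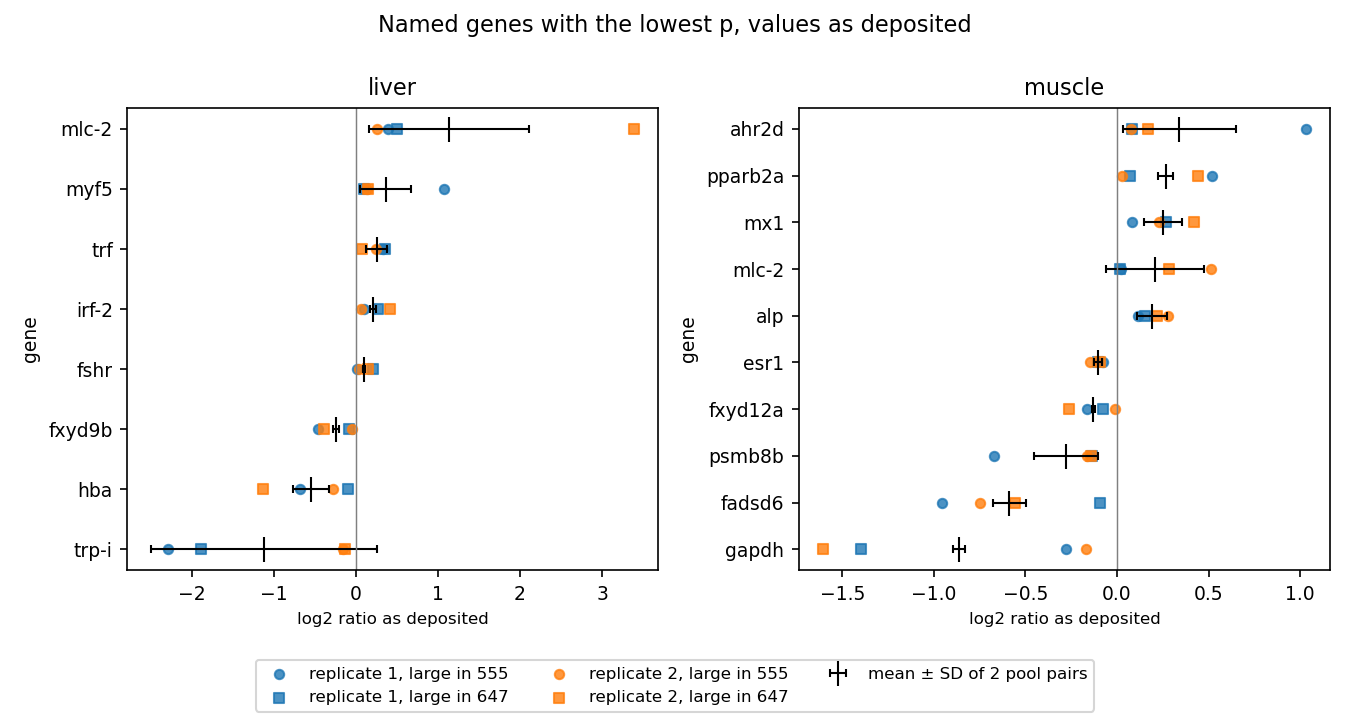
Log2 ratios as deposited (horizontal axis) of the named genes per tissue with the lowest p and 1 sign on all 4 arrays when no sign is changed; symbols and colours are as for the turned values and black marks are the mean ± SD of 2 pool pairs. The lowest mean in muscle is that of gapdh (-0.86), and in liver the probe of trp-i (-1.12) rests on replicate 1.

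Transcripts of plasma proteins that the liver makes were also measured in muscle, and were chosen after their values were seen. As deposited, the pair means of the albumin gene alb1 were 0.66 in replicate 1 and -0.93 in replicate 2, those of antithrombin 0.32 and -0.64, and those of 3 transferrin (trf) probes 0.18 to 0.79 and -1.44 to -0.79. Of the 3 probes of the globin gene hba, which marks red blood cells, 2 ran the same way, with 0.25 and 0.30 in replicate 1 and -0.51 and -0.50 in replicate 2. These are opposite deviations of both pool pairs, and the turned values of the plasma protein probes were negative in both, from -0.38 to -0.13 in replicate 1 and from -0.40 to -0.03 in replicate 2.

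**Figure D3:**
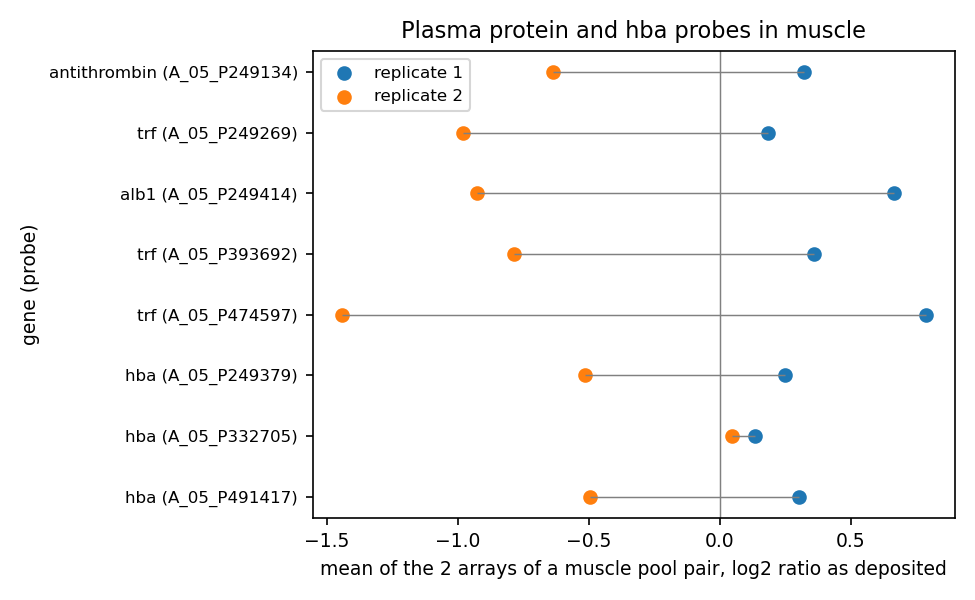
Mean of the 2 deposited log2 ratios of a muscle pool pair (horizontal axis) for each probe of alb1, trf, antithrombin and hba (vertical axis), with replicate 1 in blue and replicate 2 in orange. All 5 plasma protein probes are positive in replicate 1 and negative in replicate 2, and the lowest is a trf probe at -1.44.

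The last comparison set the liver ratio against the muscle ratio. In limma 0 of 34,757 probes passed, with 3118 at an unadjusted p under 0.05 against 1737.9 expected and a lowest adjusted p of 0.546. With the replicate number as a block 0 passed as well, with 2139 at an unadjusted p under 0.05, and with the values taken as already turned 0 passed, with 1718. Without liver replicate 1 or 2, 4533 or 4117 passed. Of the named genes of the rule, brd2 had a turned difference of 1.88 (liver minus muscle) and spp2 one of 1.11, each with an adjusted p of 0.546. With no sign changed these differences were 1.87 and -0.05, while a probe of trp-i had -1.29 and a probe of mlc-2 had 1.19, against 0.02 and -0.69 turned. The labels do not say whether liver and muscle pools of one number came from the same fish.

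Few of the fixed gene lists could be tested, because the platform annotation gave only 93 symbols other than placeholders. The interferon response and antigen presentation list had 9 genes, 7 of them measured in every pool pair. In liver 4 of the 7 had positive and 3 negative turned means and none passed, among them mx2 at -0.42, b2m, a subunit of class I histocompatibility molecules, at -0.61 ± 0.77, and psmb8b at 0.17 ± 0.07. The median of the list was 0.03 and its mean -0.12, and camera gave an adjusted p of 0.40, or an adjusted p of 0.478 with an estimated correlation. Fry gave a directional p of 0.150 and a mixed p of 0.0350. It tests the genes against 0 and not against other probes. Since 7346 of 36,053 liver probes had an unadjusted p under 0.05 in limma, the mixed p is not particular to this list. In muscle 3 of 9 genes were positive and 6 negative, with tap2b, a peptide transporter, at 0.25 ± 0.07 and psmb9a at 0.23 ± 0.18. Camera there was run on the 7 genes measured in every pool pair of both tissues, without psmb9a and tap1, and gave an adjusted p of 0.782, or 0.803 with an estimated correlation, and fry gave 0.913 and a mixed p of 0.453. With the values taken as already turned, camera gave 0.900 in liver and 0.714 in muscle. Adjusted over the list alone, 0 genes passed in either tissue, with limma's lowest adjusted p at 0.0580 in liver.

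The other lists had too few genes for a set test. Of the growth hormone and IGF axis, igfbp6, which binds insulin-like growth factors, had a turned mean of -0.36 ± 0.16 in liver and -0.20 ± 0.16 in muscle, and the growth hormone receptor ghr1 had -0.08 in muscle. Its values were incomplete in liver, and igf1, igfbp1, mstn and vtg had no probe of that name. Of glycolysis and gluconeogenesis, pck2 had a gene-level mean of -0.65 ± 0.04 in liver and -0.15 ± 0.20 in muscle, and gapdh had -0.33 ± 0.71 in liver. Of oestrogen-induced egg proteins esr1 had -0.53 ± 0.31 in liver and -0.08 ± 0.23 in muscle. The cytosolic ribosomal protein gene rps7 had -0.04 ± 0.05 in muscle, and pparg, on the lipid and the adipocyte list, had 0.15 ± 0.36 in liver and 0.17 ± 0.20 in muscle. The red blood cell marker hba had -0.03 ± 0.40 in liver and -0.11 ± 0.15 in muscle. Adjusted over the list alone, igfbp6 and esr1, each the only measured gene of its list, and pck2 passed 0.05 in liver (0.0364, 0.0277 and 0.00745 in limma), whereas over all probes 0 genes of these lists passed. For igfbp6 and esr1 this adjustment changes nothing. In the same fit 7346 of 36,053 liver probes had an unadjusted p under 0.05. With no sign changed the liver means of igfbp6 and of 1 pck2 probe had the other sign (0.08 and 0.13), and only gapdh in muscle passed over its list alone (0.00160). Oxidative phosphorylation, protein breakdown, cell cycle, collagens, exocrine pancreas and leukocyte lists had 0 genes among the symbols of the annotation. Whether unnamed probes measure such genes is unknown. The myofibril, plasma protein and chaperone lists had 0 by symbol.

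The agreement of both pool pairs was compared across probes, which are not independent replicates. The turned values of replicates 1 and 2 correlated with r = 0.206 in liver and 0.316 in muscle. As deposited, with no sign changed, the correlations were 0.083 and -0.095. Between liver and muscle pool pairs the turned values correlated with 0.096 to 0.264 and the means without turning with 0.008 to 0.070, the reverse of what the design expected of a dye effect. All 4 turned arrays had one sign for 26.2% of the liver probes and 17.2% of the muscle probes, and all 4 deposited values for 9.6% and 10.6%. Chance gives 12.5% if the array medians are 0 and the 4 arrays vary independently. The arrays of a pool pair hold the same RNA, so they need not vary independently. In liver the turned share comprised 6382 positive and 3067 negative probes, since the turned medians were all positive. With each array centred on its median, a step added after seeing the data, the turned shares were 24.1% and 16.9%, with 3962 positive and 4738 negative probes in liver. The dye effect itself, the mean without turning, is the same fit as that with no sign changed, so it too passed 0 probes in limma in either tissue, with 3596 and 680 at an unadjusted p under 0.05, or 1531 and 1239 with each tissue fitted alone, so the gap between the tissues comes with the shared spread.

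**Figure D4:**
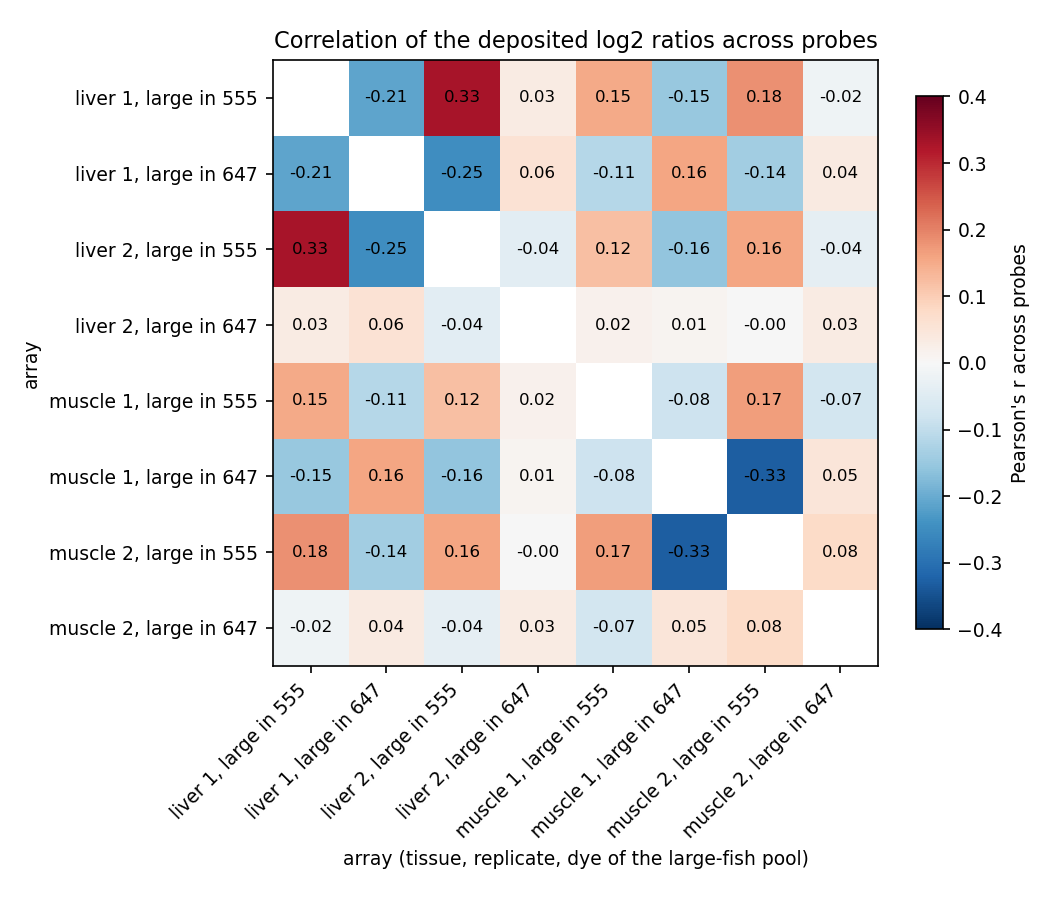
Pearson correlation across probes between the deposited log2 ratios of each 2 arrays, with tissue, replicate and the dye of the large-fish pool on both axes. Arrays of the liver with large fish in the 555 dye correlate at 0.33, the lowest value is -0.33 between 2 muscle arrays, and the array of liver replicate 2 with large fish in the 647 dye lies between -0.04 and 0.06 with all others.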

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

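The tests of explanations in this part were chosen after the result was seen, except that on liver RNA, whose bounds were fixed first but whose reading was changed afterwards.

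The array of muscle replicate 1 with large fish in the 555 dye stood apart from the other muscle arrays in spread, with a standard deviation of 0.333 against 0.318 to 0.320. It was the only one of 65 groups of 4 arrays with an outlying array, where chance gives about 1 in 20, or 3.2. For 3 genes all 4 turned liver arrays had one sign and all 4 turned muscle arrays the opposite one. The means were -0.42 in liver and 0.09 in muscle for mx2, 0.48 and -0.13 for gnrh, and 0.37 and -0.12 for tyrp-1b. The test of the liver against the muscle ratio in limma gave each of them an adjusted p of 0.546, so a difference between tissues was not shown. With no sign changed the means were -0.07 and -0.04 for mx2, 0.14 and -0.03 for gnrh, and -0.01 and 0.03 for tyrp-1b.

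Large deviations in muscle replicate 2 kept their sign when the dyes were exchanged. Of its 14 probes beyond 1.5 on both arrays 14 had one sign on both, as had 64 of 79 beyond 1.0 and 5 of 5 beyond 2.0, while for replicate 1 it was 26 of 55 beyond 1.0, 5 of 9 beyond 1.5 and 3 of 3 beyond 2.0. In liver opposite signs prevailed beyond 1.5, at 119 of 171 probes in replicate 1 and 94 of 150 in replicate 2, but beyond 2.0 replicate 1 was near even, at 17 of 33. If the deviations of replicate 2 were dye bias of the probes, most should recur in replicate 1. A size difference shared by both pool pairs would recur as well if the values were already turned. But 3 of the 14 probes were beyond 0.5 with that sign on both arrays of replicate 1, among them 2 of LOC100136569. For the 3 that recurred the count cannot tell dye bias from a shared size difference. It argues against either as the reason for most of the 14 probes, but does not settle whether the values were already turned. Control spots, for which the bound against dye bias was tightened once their values were known, left the question open, since 66.3% of them had opposite signs in liver (ordinary probes 65% and 53% in its pool pairs) but 45% and 46.7% in the muscle pool pairs (ordinary probes 53.4 and 48.5%). The blank control spots changed sign wherever both arrays of a liver pair had a value, and their turned values there were positive. DarkCorner had 0.76 and -1.26 in replicate 1 and 0.71 and -0.12 in replicate 2, and (-)3xSLv1 had 0.92 and -2.81 in replicate 2. In muscle DarkCorner had 0.32 and -0.48, then 0.52 and 0.58, and (-)3xSLv1 -0.04 and -0.04, then 0.22 and -0.07. Blank spots hold no size difference, so the turned liver values may hold a part other than size. It therefore stays open whether the deposited muscle values were already turned, or whether the tissues were treated alike. A difference in size in replicate 2 alone is untested as a reason.

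Transcripts of plasma proteins made by the liver deviated in opposite directions in the 2 muscle pool pairs, from 0.18 to 0.79 in replicate 1 and from -1.44 to -0.64 in replicate 2 as deposited. If the values were already turned, a size difference shared by both pool pairs would put the probes on one side. As deposited 0 of 5 probes of alb1, antithrombin and trf lay on the same side in both pairs. That count restates the pattern for which they were chosen, so it is no separate test. If the values were not turned, a size difference would cancel in these means, and turned, 5 of 5 probes lay on the same side. Dye bias of the probes would part the 2 arrays of a pair if the values were already turned, but 9 of 10 combinations of probe and pair had one sign on both. If the values were not turned, it would recur in both pairs, as it did at 0 of 5 probes. That count again only restates the pattern. Blood was taken to move hba at least as far, but its largest difference between the pairs was 0.798 against 0.961 for the lowest plasma protein probe. The other hba probes differed by 0.764, in the same direction, and 0.089. Differences of probes whose intensities are unknown need not match, so this comparison does not exclude blood. It also assumes that blood holds transcripts of these proteins, which the liver makes, and that was not tested. Liver RNA in some muscle pools may still be the source if the values were already turned: 30 further probes with this pattern had a median turned liver value, a dye part if the deposited values were already turned, at percentile 28.9 of all probes, inside the middle range that was set beforehand as arguing against it, but the plasma protein probes themselves had a median of -0.01 there, above the 25th percentile of -0.20, so that measure does not mark liver transcripts.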

How the results depend on the processing

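The fit with replicate 2 of liver from 1 array and the fits of each tissue alone with no sign changed were added after seeing the data. So were the lists extended by aliases and the shares of probes with one sign on centred arrays. Fits of all 8 arrays count the 2 arrays of a pair, which hold the same RNA, almost as separate replicates. With them the liver count of 0 became 159 with the pool pair as a random block and 138 with the arrays as independent. A dye effect of replicate 2 does not cancel when only its array with large fish in the 555 dye is used. With that array alone the liver count was 1539, for a cause not tested. Without 1 pool pair it ranged from 0 to 7964, the muscle count from 0 to 3 and the liver minus muscle count from 0 to 4533. By construction the lone liver pool pair is then assumed to vary like muscle, whose spread is smaller. The muscle count was 3 when fitted alone and 1 after scaling, and the cause was not tested. Centring, both filters, robust moderation, the gene level, the unchanged sign and a threshold of 0.10 left all 3 counts at 0. The agreement of the liver pool pairs was 0.287 by Spearman's coefficient, 0.329 and 0.059 between single arrays with large fish in the 555 and the 647 dye, and 0.083 with no sign changed; in muscle the last 3 were 0.166, 0.048 and -0.095. Camera's adjusted p for the interferon list ranged from 0.188 to 0.932 in liver and from 0.667 to 0.965 in muscle. Of the values of named genes under the alternatives, 844 kept their sign and side of the threshold, 27 came under it, and 68 changed sign without passing. Many alternatives leave the mean of a gene as it was, so its sign could not change there and the 844 do not measure robustness of the sign. Signal over background was not analysed here.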

Other observations

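The tests of this part were chosen after the result was seen. Some genes outside the naming rule were looked at for their role in muscle, growth and lipid metabolism. The myogenic gene myod1 had a turned mean of -0.43 ± 0.20 (SD, n = 2 pool pairs) in muscle, with an adjusted p of 1 in limma, beside -0.48 for mrf4 and -0.10 ± 0.03 for myf5. The myostatin gene gdf-8 had -0.15 ± 0.20 in muscle. The desaturase fadsd5 had -0.54 ± 0.14 in muscle and -0.45 ± 0.60 in liver. Of the chaperones, hsp70 had -0.49 ± 0.12 in liver and -0.03 ± 0.77 in muscle. With no sign changed, the muscle means of myod1, mrf4, myf5 and gdf-8 were positive (0.17, 0.07, 0.03 and 0.05), as were those of hsp70 (0.29 in liver and 0.17 in muscle), so their signs rest on the reading. For fadsd5 these means were -0.45 ± 0.21 in liver and -0.49 ± 1.09 in muscle, with 0.28 in replicate 1 and -1.26 in replicate 2. Adding aliases of this kind to the interferon list gave camera an adjusted p of 0.911 in liver and 0.906 in muscle.

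In liver the turned part ran with how often a probe was missing. Its median in replicate 1 was 0.08 for the 36,053 probes measured on all liver arrays and 0.26 for 365 probes missing on both arrays of replicate 2. The difference of 0.184 may reflect dye differences by intensity left after the authors' normalization, but it lies between the bounds set for and against that, and no intensities were used here.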
